A study of Mus musculus with 16 samples.

How the data were processed

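The series measured RNA of single Lin–Sca1+Kit+ (LSK) cells, the bone marrow fraction that holds haematopoietic stem cells and multipotent progenitors. Per the labels, lethally irradiated CD45.1/CD45.2 mice had received control (CD45.1) and Regnase-1/Regnase-3 double knockout (CD45.2) fetal liver cells in equal parts, and LSK cells were sorted one per well at 4 weeks. Libraries of mRNA 3' ends were made by MARS-seq, a plate method in which each transcript carries a unique molecular identifier (UMI), per the labels' protocols. The authors deposited molecule counts per gene and well for 16 libraries of 384 wells each, not normalized, and a table that gives the position, sequencing batch and number of cells of each well. Per the submitters' processing notes, bcl2fastq 2.15.0.4 was used and the build was mm10. The aligner, the counting tool, its use of strand and the annotation are not given in the sources used here.

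The labels put all 16 libraries in 1 group, and the well table names neither a genotype nor a mouse. No knockout against control comparison was therefore made, and no library or cell was given a genotype from its expression. Instead each library's value is given with the range and the median, as had been set for this case. The well table covered 5760 wells of 15 libraries, with 9 libraries in sequencing batch SB341 and 6 in SB343. LSK library 1 had no entry there, so no batch is given for it.

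Of 52542 gene entries other than the 92 spike-in entries, 48106 carried a symbol of the gene name table used here. A well was kept as a cell when the well table did not give it as empty, it held at least 500 UMIs and under 20% of its UMIs were mitochondrial. This left 5157 cells, and 86 wells with enough UMIs were over the mitochondrial maximum. The 60 wells listed as empty held 801 UMIs together, 0.00803% of the UMIs of their libraries, and at most 34 in a well. Wells in the well table were listed with at most 1 cell, so no doublet caller was run. For LSK library 1 the number of cells per well is not known. Over the 120 pairs of libraries, the chi-square of gene counts per degree of freedom was 1.64 to 12.5. The same counts deposited again would give a value near 0, so no library was taken as a second copy of another. UMIs of the same cell are not independent, so values above 1 would also arise between plates of cells from the same mouse, and they say nothing on whether libraries share a mouse.

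Cells were clustered with scanpy 1.11.5 in Python 3.11.15 on 2000 variable genes chosen per library, 30 principal components, 15 neighbours and the Leiden method at resolution 1.0. Cell cycle, ribosomal, mitochondrial and sex-linked genes and the Regnase genes were kept out of the clustering. A cluster was named after a cell type when at least 3 of that type's markers were raised at least 2-fold in it and its leading genes did not go against the name. Markers of 11 cell types were set before the data were examined, as were the cell filter, the clustering resolution, 24 gene lists, the rule for named genes and the alternatives for values per library. The filter had been set for wells listed with 1 cell. LSK library 1, which the well table lacks, was kept by UMIs and mitochondrial share alone, a change made afterwards.

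The comparisons between cell classes, and all their alternatives, were chosen after the data were seen. UMIs were summed per library and class where a class held at least 10 cells, and pairs of sums from the same library were tested with edgeR 4.0.16 in R 4.3.3. The model was the quasi-likelihood F test with TMM factors, filterByExpr and the library as a block, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The pairing comes from the library itself, since both sums of a pair came from the same plate of wells. Genes used for clustering, all markers and the 10 leading genes of each named cluster entered the sums but were not tested. They were left out because they define the classes, except the markers of cycling cells, which served neither to cluster nor to name. These cycling markers took 8 of the 46 G2 to M phase genes out of the tests, among them the most abundant, Hmgb2 and Top2a. Cells were placed in classes by their own expression, so genes that vary together with the clustering genes differ between classes by construction, and the p-values are too small by an unknown amount. They measure the spread between libraries; the number of mice is not given in the sources used here, and libraries may share mice. The 4 comparisons share class sums and are not independent.

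Gene lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The 24 lists were Regnase target mRNAs described in other cells, NF-kB feedback, HSC, myeloid, lymphoid, megakaryocyte and erythroid, mast cell and basophil, dendritic cell, MHC class I, interferon response, G1 to S phase, G2 to M phase, quiescence, immediate early and dissociation stress, mature neutrophil and macrophage, mature B cell, T and NK cell, erythroid and platelet, endothelial and stromal, sex-linked, Regnase family, ribosomal protein, mitochondrially encoded and glycolysis genes. Named genes were Zc3h12a, Zc3h12c and Nfkbiz, up to 4 tested members of each list with the smallest p, and the 6 largest rises and 6 largest falls. The last were taken from called genes with a symbol, a mean of at least 20 CPM and the same direction in at least 75% of the pairs. Gene coordinates are from GENCODE vM21 on GRCm38, the assembly that mm10 names.

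CPM, the counts of a gene scaled to 1e+06 UMIs of the library, were computed from the deposited counts over all gene entries of the kept cells. Intervals for shares of cells are 95% Wilson intervals, the limit of a count of 0 is 3 counts, and both cover counting error only. Class depths and shares of list UMIs were compared with paired permutation tests, two-sided. In counts simulated from the sums, with 200 genes changed, the test called 80% of the genes changed 1.5-fold between neutrophil and monocyte-like and lymphoid-like cells (1414 genes). It called 96.6% between lymphoid-like and HSC-like cells (557 genes), 86.9% between neutrophil and monocyte-like and HSC-like cells (795 genes) and 95.5% between megakaryocyte and erythroid-like and HSC-like cells (511 genes). Of genes simulated without a change, the test called 8 of 1242, 8 of 392, 6 of 633 and 22 of 339 in the same order. In the last the median log2 fold change of unchanged genes was -0.07, a shift of scaling in counts where 200 genes had been changed. Whether the real sums hold such a shift was not tested, so small falls there are to be read with care. A list raised 1.41-fold was called in each of the 4, and 0 of 20 unchanged lists were. Genes were simulated independently of each other and with fixed class labels. The simulation therefore does not measure false calls from correlated genes or from classes made from the tested cells.

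Alternatives were UMI minimums of 300 and 1000, clustering resolutions of 0.5 and 1.5, other clustering genes, DESeq2 1.42.0, RLE factors, no filter on low counts, no block, cells thinned to 500 UMIs, sums without mitochondrial and ribosomal genes, each batch alone and each library left out.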

Results

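Single LSK cells from the bone marrow of transplanted mice were profiled 4 weeks after lethally irradiated hosts had received a mixture of control and Regnase-1/Regnase-3 double knockout fetal liver cells. Regnase-1, encoded by Zc3h12a, is an RNase that degrades mRNAs of immune genes, and Regnase-3, encoded by Zc3h12c, belongs to the same family. The study asked how the loss of both changes the transcripts of LSK cells. Genotype was not given for any library or well in the sources used here, so that question was not analysed here. The values below describe the 16 libraries, which the labels put in 1 group, and the cell classes found in them. Some values lay in separate ranges over the libraries, as given under other observations. The class comparisons draw on all libraries with enough cells, and whether they agree between those ranges was not tested.

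The 16 libraries held 521435 to 822534 UMIs, with a median of 660720. Between 295 and 345 cells per library were kept, with a median of 323.5. The median UMIs per kept cell ranged from 1146 to 1993 over libraries, and the median genes per kept cell from 619 to 1071. Mitochondrial transcripts made up 9.46% to 12.4% of UMIs. Wells listed as empty held a median of 6 to 18 UMIs per library, and none of them reached 500.

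The transcripts of both targeted genes were present in every library, at levels near the limit of detection. Zc3h12a (chromosome 4, 125118423 to 125127840, minus strand, GRCm38) had 1 to 11 UMIs per library and 93 in all, in 81 of 5157 cells (1.57%, 95% Wilson interval 1.27% to 1.95%). Its level had a median of 8.86 CPM over libraries and a range of 1.57 to 17.4 CPM. Zc3h12c (chromosome 9, 52111344 to 52168572, minus strand) had 2 to 12 UMIs per library and 77 in all, in 65 of 5157 cells (1.26%, interval 0.99% to 1.60%). Its level had a median of 6.34 CPM and a range of 2.55 to 15.5 CPM. The tags come from mRNA 3' ends, and the 3' UTR of Zc3h12a lies at 125118423 to 125119281 and that of Zc3h12c at 52111985 to 52115408. The deleted parts are not given in the sources used here, so a tag may lie outside them and checks no genotype. The Regnase family list as a whole stood at a median of 81.7 CPM (44.0 to 111), with N4bp1 at 31.9 CPM and Khnyn at 18.6 CPM as its most abundant members.

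Nfkbiz encodes a nuclear IκB protein and its mRNA is a known Regnase-1 target. It lies on chromosome 16, 55811375 to 55838899, minus strand, and had 206 UMIs in 169 of 5157 cells (3.28%, interval 2.83% to 3.80%). Its level ranged from 0 to 52.0 CPM over the libraries, with a median of 12.5 CPM. That median lay in a gap, since libraries 1 to 8 had 0 to 4 UMIs and libraries 9 to 16 had 12 to 36. LSK libraries 6 and 7 had 0 UMIs of it, which allows up to 4.72 CPM and 4.17 CPM. Over the Regnase target list, 23 of 29 genes had a UMI and the sum had a median of 443 CPM (340 to 574). The most abundant were the blood cell transcription factors Gata2 at 89.7 CPM and Tal1 at 65.2 CPM, the transferrin receptor gene Tfrc at 55.5 CPM and Batf at 27.3 CPM. The NF-kB feedback list stood at 581 CPM (490 to 667), led by Nfkb1 at 117 CPM and Irf1 at 69.6 CPM.

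**Figure D1:**
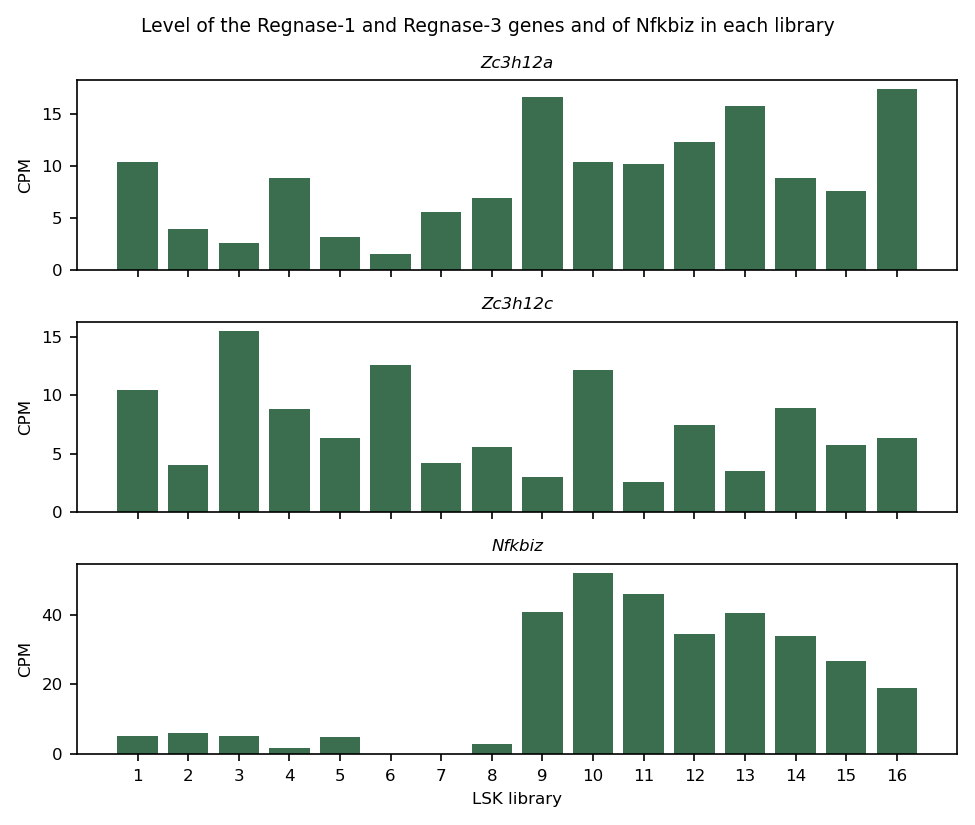
Level of Zc3h12a, Zc3h12c and Nfkbiz in CPM of all UMIs of the kept cells, with 1 bar for each of the 16 LSK libraries. Zc3h12a lies between 1.57 and 17.4 CPM, Zc3h12c between 2.55 and 15.5 CPM and Nfkbiz between 0 and 52.0 CPM; no label ties a bar to a genotype.

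Transcripts of several blood lineages were measured in the LSK cells, each list given as its median and range over the 16 libraries. The HSC list, led by Ifitm3 and Ifitm1, stood at 2305 CPM (1836 to 2543), and the lymphoid list, led by Dntt, at 2568 CPM (2129 to 3210). The myeloid list, led by Calr and Mpo, stood at 2602 CPM (1710 to 4321). The megakaryocyte and erythroid list, led by Car2 and Nfe2, stood at 1768 CPM (1406 to 2462). Mast cell and basophil genes, led by Cpa3, reached 60.8 CPM (29.1 to 91.9) and dendritic cell genes, led by H2-Aa, 377 CPM (218 to 683). MHC class I genes, led by B2m, stood at 8378 CPM (7619 to 9206) and interferon response genes, led by Ly6e, at 3221 CPM (2950 to 3636). G1 to S phase genes, led by Pcna, stood at 4583 CPM (4229 to 5106), and G2 to M phase genes, led by Hmgb2, at 6060 CPM (4343 to 7362). Quiescence genes, led by Txnip, stood at 507 CPM (407 to 632). Immediate early and dissociation stress genes were led by the chaperone genes Hsp90aa1, Hspe1 and Hspa8, at 2046 CPM (1596 to 2592). Glycolysis genes stood at 2168 CPM (1927 to 2441), ribosomal protein genes at 110230 CPM (105050 to 118048) and mitochondrially encoded transcripts at 102940 CPM (94329 to 120851).

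Lists of genes of other cells that may enter the LSK gate stood low. Nkg7, Cd79b and Hbb-bt, which led some of them, are also members of the myeloid, lymphoid, and megakaryocyte and erythroid lists. Their UMIs alone therefore do not measure cells from outside the gate. Mature neutrophil and macrophage genes stood at 37.5 CPM (14.2 to 156), led by Axl at 11.3 CPM. Mature B cell genes stood at 48.0 CPM (25.2 to 70.7), nearly all of it Cd79b at 39.9 CPM. T and NK cell genes stood at 188 CPM (108 to 234), led by Nkg7 at 148.5 CPM. Erythroid and platelet genes stood at 166 CPM (118 to 400), led by the globin gene Hbb-bt at 137.9 CPM, and endothelial and stromal genes at 60.0 CPM (32.4 to 172), led by Pecam1 at 47.9 CPM. Sex-linked genes stood at 68.9 CPM (26.0 to 113), and transcripts of the Y-linked Ddx3y and Eif2s3y were found in every library.

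Clustering gave 11 clusters, of which 4 could be named. A cluster of 721 cells led by Ctsg, Mpo, Ly6c2 and Prtn3, genes of neutrophil and monocyte granules and surface, was called neutrophil and monocyte progenitor-like. A cluster of 664 cells led by Dntt, Ighm, Il12a, Notch1 and Flt3 was called lymphoid-primed progenitor-like. Cox6a2, a listed dendritic cell marker, was also among the leading genes of that cluster. A cluster of 557 cells whose leading genes included Mecom, Pdzk1ip1, Hlf and Procr, genes of stem cells, was called HSC-like. Hbb-bt and Cd74, genes of erythroid and antigen-presenting cells, were also among its leading genes. A cluster of 451 cells led by Car1, Pf4, Apoe and Gata1 was called megakaryocyte and erythroid progenitor-like. The other clusters stayed unnamed. They held 998 cells with few UMIs (median 930), 571 cells led by histone genes such as Hist1h1e and Hist1h1b, and 537 cells led by Hist1h2bc. Further ones held 433 cells led by Ung, Dph1 and Chek1, 126 cells led by Gm23935, 68 cells led by Ifit1, Rsad2 and Serpina3f, and 31 others. Cells rich in histone transcripts, and those led by the G1 to S phase gene Ung, were thereby partly held in clusters outside the named classes. At resolution 0.5 Hist1h1e and Hist1h1b were among the leading genes of the megakaryocyte and erythroid progenitor-like cluster. All comparisons of cell cycle genes below cover only cells left in the named classes, which depends on the clustering. No cluster was called HSC-like at resolution 0.5, with pooled variable genes or without histone and state genes in the clustering, so that the 3 comparisons against HSC-like cells were not made there.

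Over the 16 libraries, HSC-like cells made up a median of 10.6% of kept cells (5.07% to 20.2%). Lymphoid-primed progenitor-like cells made up 12.1% (7.04% to 20.4%), neutrophil and monocyte progenitor-like cells 12.3% (2.75% to 26.4%) and megakaryocyte and erythroid progenitor-like cells 7.57% (3.88% to 15.5%). The neutrophil and monocyte median lay in a gap between 8.96%, the highest of libraries 1 to 8, and 15.7%, the lowest of libraries 9 to 16. The megakaryocyte and erythroid median lay between 6.67% and 8.47% in the same way. Cells of unnamed clusters made up 52.4% (41.7% to 72.2%). The low-UMI cluster alone took 4.64% to 52.3% of a library. Its share was lower in libraries with more UMIs per kept cell (Pearson r = -0.672, permutation p = 0.0032). Without libraries 2 and 12, the farthest in UMIs, r was -0.46 (permutation p = 0.097). Within batch SB341 r was -0.901 (permutation p = 0.00022) and within SB343 -0.88 (permutation p = 0.011). Spearman's rho was -0.574 over all libraries (permutation p = 0.023) and -0.363 without libraries 2 and 12 (permutation p = 0.2). It was -0.933 within SB341 (permutation p = 0.00075) and -0.829 within SB343 (permutation p = 0.058). These tests were not set beforehand. Cells of the low-UMI cluster count in their library's median UMIs, so a larger share lowers that median by construction. The tests therefore cannot show how far depth sets the share of that cluster. None of them related the shares of named classes to depth.

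**Figure D2:**
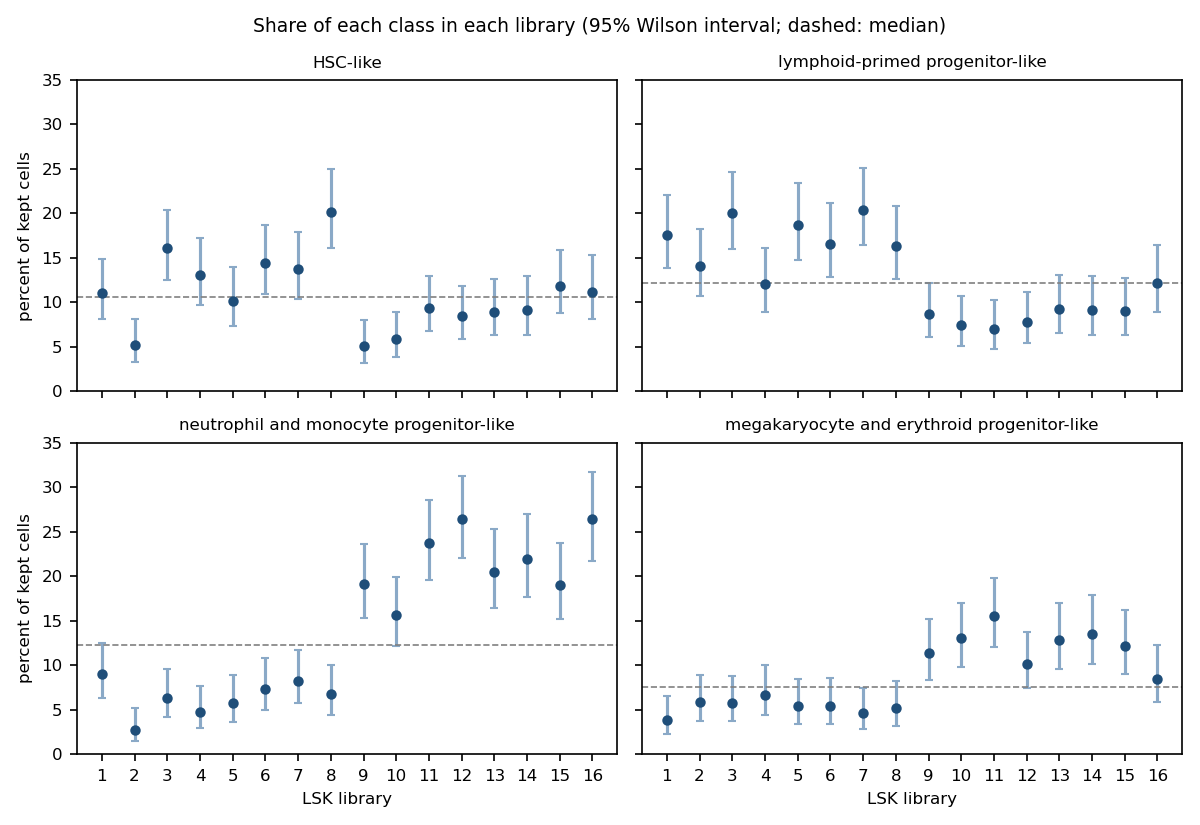
Share of kept cells in each named class (percent) against LSK library number, with 95% Wilson intervals as bars and the median over the 16 libraries as a dashed line. Neutrophil and monocyte progenitor-like cells range from 2.75% to 26.4% and lymphoid-primed progenitor-like cells from 7.04% to 20.4%; the bars cover counting error only.

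HSC-like cells held the fewest transcripts of the named classes and the highest share of mitochondrial ones. Over 15 libraries, neutrophil and monocyte-like cells had a median of 2738 UMIs against 1755 in lymphoid-like cells and 1301 in HSC-like cells, higher in 15 of 15 libraries in both comparisons (permutation p = 6.1e-05, the smallest it can give; adjusted p = 8.14e-05 over 16 tests). Lymphoid-like cells had 1754 UMIs and megakaryocyte and erythroid-like cells 1846.5 UMIs against 1286.5 in HSC-like cells, higher in 16 of 16 libraries in both (permutation p = 3.05e-05, the smallest it can give; adjusted p = 8.14e-05). The mitochondrial share was 12.2% in HSC-like cells against 10.6% in lymphoid-like cells (permutation p = 0.000214, adjusted p = 0.000263; lower in HSC-like cells in 1 library). Megakaryocyte and erythroid-like cells had 9.13% (permutation p = 3.05e-05, adjusted p = 8.14e-05, 0 libraries lower in HSC-like cells). The size of these differences depended on the UMI minimum. At 1000 UMIs, neutrophil and monocyte-like cells had 2928 UMIs against 2798.5 in lymphoid-like cells, higher in 9 of 12 libraries (permutation p = 0.0142). At 300 UMIs they were higher in 11 of 13 (permutation p = 0.0129). Against HSC-like cells, UMIs stayed higher and mitochondrial shares lower in most libraries at both minimums. With each cell thinned to 500 UMIs, 340.25 genes per cell were found in HSC-like cells and 366 in megakaryocyte and erythroid-like cells, higher in the latter in 16 of 16 libraries (permutation p = 3.05e-05, adjusted p = 8.14e-05).

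Neutrophil and monocyte-like cells had more transcripts of G1 to S phase and glycolysis genes than lymphoid-like cells of the same libraries, and fewer of the lymphoid genes Mef2c and Ikzf1 and of MHC class I genes. Of 23 tested G1 to S phase genes, 10 were higher and 0 lower (15 higher adjusted over the list alone), and all 23 had a positive log2 fold change. Among them were the replication clamp gene Pcna (log2 fold change 0.53 ± 0.10 SE, n = 15 libraries, adjusted p = 2.33e-05), the helicase gene Mcm3 (0.66, adjusted p = 0.000444) and the DNA ligase gene Lig1 (0.84 ± 0.20, adjusted p = 0.000887). The single-strand binding protein gene Rpa1, outside the lists, rose by 1.01 ± 0.22 (adjusted p = 0.000333, higher in 15 of 15 libraries; 119 against 54.1 CPM). Of 7 glycolysis genes 3 rose (4 adjusted over the list alone), Pgam1 by 1.01 ± 0.14 (adjusted p = 3.29e-08), Ldha by 0.71 (adjusted p = 4.78e-08) and Pgk1 by 0.45 (adjusted p = 0.0292). Pgk1 was not called without LSK library 5, 6, 8, 12 or 14 (adjusted p = 0.0613 to 0.0873). Rpn1, a subunit of the protein glycosylation complex, rose by 0.99 ± 0.18 (adjusted p = 1.02e-05), and Lrrc59 by 0.87 ± 0.19 (adjusted p = 0.000462). The myeloid signalling adaptor gene Tyrobp rose by 0.52 (adjusted p = 0.0328), but was not called without library 3, 4, 6, 11 or 16 (adjusted p = 0.0578 to 0.0891). When variable genes were chosen over all libraries pooled it had -0.20 and was not called (adjusted p = 0.854), in a fit on 4 pairs of libraries.

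On the side of lymphoid-like cells, 2 of 4 tested lymphoid genes fell in neutrophil and monocyte-like cells (4 adjusted over the list alone), too few for a list test. They were the transcription factor genes Mef2c (log2 fold change -0.77 ± 0.15, adjusted p = 5.51e-05, lower in 14 of 15 libraries) and Ikzf1 (-0.63 ± 0.15, adjusted p = 0.00127). Of the 35 lymphoid genes 19 had served to cluster or name the classes, so falls of the others are no independent support for the name. The endothelial and stem cell gene Egfl7, which shares its locus and strand with Mir126a, fell by 1.05 ± 0.17 (adjusted p = 3.95e-07, lower in 15 of 15 libraries), and Tspan13 by 0.96 ± 0.15 (adjusted p = 6.66e-07). Of 9 MHC class I genes 2 fell (2 adjusted over the list alone), H2-K1 (-0.36 ± 0.06, adjusted p = 2.44e-06) and H2-Q7 (-0.74 ± 0.14, adjusted p = 2.54e-05, lower in 15 of 15 libraries). H2-K1 and H2-Q7 have close paralogs, and how shared tags were counted is not given. The interferon-induced Ifi203 had -0.67 (adjusted p = 6.09e-05) and overlaps Mndal on the same strand.

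Across the 1476 genes tested, 177 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 86 higher and 91 lower in neutrophil and monocyte-like cells, 24 of them gene models without a symbol. By camera, the G1 to S (adjusted p = 1.22e-08), glycolysis (0.00046), immediate early and stress (0.0224), MHC class I (0.0114) and ribosomal protein lists (5.28e-08) were called. All 5 held with an estimated correlation (adjusted p = 0.00955, 0.00955, 0.0386, 0.0386 and 0.00955). The MHC class I list was not called within batch SB343 (adjusted p = 0.0833, 6 pairs of libraries) or with pooled variable genes (0.628, 4 pairs). In the immediate early and stress list the members that rose were Hsp90aa1 (0.44, adjusted p = 1.02e-05) and Hspe1 (0.33, adjusted p = 0.0177), both chaperone genes and neither an immediate early gene. Hspe1 was not called without library 7, 8 or 16 (adjusted p = 0.0519 to 0.058). Without a filter on low counts that list's median was -0.13. Of 14 G2 to M phase genes 2 were lower, Cenpa (-0.79) and Ccnb2 (-0.58) (2 adjusted over the list alone). The list was not called (adjusted p = 0.133) but was, as lower, with a minimum of 300 or 1000 UMIs per cell (adjusted p = 0.0136 and 2.8e-11), without histone and state genes in the clustering (0.00528), within batch SB341 (0.0236) and without library 1 (0.0244). With pooled variable genes, a fit on 4 pairs of libraries instead of 15, its median log2 fold change was 0.25, with 8 of 11 genes above 0. Its share of all UMIs had a median log2 ratio of -0.06 (permutation p = 0.684) and of 0.08 in thinned cells (permutation p = 0.657). No direction can therefore be given for the G2 to M phase list. Ribosomal protein genes had a median of -0.10, with 16 of 67 lower and 0 higher (18 lower and 1 higher adjusted over the list alone), but a median of 0.03 without a filter on low counts, where the median of all genes was 0.05. With each cell thinned to 500 UMIs, 19 of 191 tested genes were called. Within batch SB341 alone 71 were called and within SB343 alone 61.

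Lymphoid-like cells had more transcripts of the tested lymphoid genes and of Cd93 than HSC-like cells, and fewer of Vamp8, Nedd4 and Adgrg1. All 4 tested lymphoid genes rose (4 adjusted over the list alone). The tetraspanin gene Cd53 had a log2 fold change of 0.92 ± 0.19 (SE, n = 16 libraries, adjusted p = 0.000158, higher in 16 of 16 libraries). The others were Ikzf1 (0.80, adjusted p = 0.000575), Mef2c (0.71, adjusted p = 0.00105, higher in 16 of 16 libraries) and Ramp1 (0.52, adjusted p = 0.00233). Of the 35 lymphoid genes 19 had served to cluster or name the classes, so rises of the others are no independent support for the name. Cd53 was also called higher in neutrophil and monocyte-like than in HSC-like cells, the 1 called of 3 tested lymphoid genes there. The largest rise was of Cd93, a surface receptor of early progenitors, at 1.07 ± 0.17 (adjusted p = 1.92e-06, 292 against 105 CPM, higher in 16 of 16 libraries). Of 4 G2 to M phase genes 3 rose (4 adjusted over the list alone), among them the condensin gene Smc4 (1.04 ± 0.18, adjusted p = 4.43e-06), which holds Mir15b and Mir16-2 in its introns, and the tubulin gene Tubb4b (0.63, adjusted p = 0.000927). HSC-like cells in turn had more of the vesicle fusion gene Vamp8 (-1.24 ± 0.15, adjusted p = 7.49e-10), the ubiquitin ligase gene Nedd4 (-0.96 ± 0.16, adjusted p = 2.57e-06) and Adgrg1, an adhesion receptor of stem cells (-0.78 ± 0.09, adjusted p = 1.07e-11), each lower in lymphoid-like cells in at least 14 of 16 libraries.

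In this comparison 88 of 608 genes were called by edgeR with Benjamini-Hochberg adjustment, 44 higher and 44 lower, 18 of them without a symbol. Among 5 glycolysis genes Aldoa fell (-0.76 ± 0.16, adjusted p = 0.000327; 3 fell adjusted over the list alone), and the list was not called (adjusted p = 0.0741) but was, as lower, without library 1, 3 or 8 (adjusted p = 0.0449, 0.0477 and 0.04997). Mitochondrially encoded transcripts were called lower (adjusted p = 0.00078) but not with an estimated correlation (adjusted p = 0.123), at a minimum of 1000 UMIs (0.145) or within batch SB343 (0.056). The members called lower were the ribosomal RNAs mt-Rnr2 (-0.36 ± 0.05, adjusted p = 4.77e-09) and mt-Rnr1 (-0.29 ± 0.05, adjusted p = 1.92e-06), 2 of 13 (4 adjusted over the list alone). Of the 13, 11 had a negative log2 fold change. Without a filter on low counts the list's median of 0.20 equalled the median of all genes. Of 59 ribosomal protein genes 10 were lower and 1 higher (10 and 1 adjusted over the list alone), and no direction can be given for them. Camera called the list lower (adjusted p = 0.00259), but not with an estimated correlation (adjusted p = 0.123), at a minimum of 300 UMIs (0.0642) or within batch SB343 (0.168). Their share of all UMIs had a median log2 ratio of 0.03 (permutation p = 0.0866, adjusted p = 0.113 over 17 tests). With each cell thinned to 500 UMIs it was 0.05, higher in 15 of 16 libraries (permutation p = 0.00128, adjusted p = 0.00272), the opposite direction to camera's. G1 to S phase and MHC class I genes had 0 of 5 and 0 of 6 called (0 and 0 adjusted over the list alone), with list adjusted p = 0.308 and 0.57. The share of UMIs of the 5 G1 to S phase genes had a median log2 ratio of 0.28 (permutation p = 0.0466, adjusted p = 0.066). In thinned cells it was 0.30, higher in 13 of 16 libraries (permutation p = 0.00317, adjusted p = 0.00491). Thinned cells gave 8 calls among 170 genes tested, and the fit without a filter on low counts gave 363 among 16096. Of the latter 331 were higher and 32 lower, with the median of all genes at 0.20. Batch SB341 alone gave 86 calls and SB343 alone 6.

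**Figure D3:**
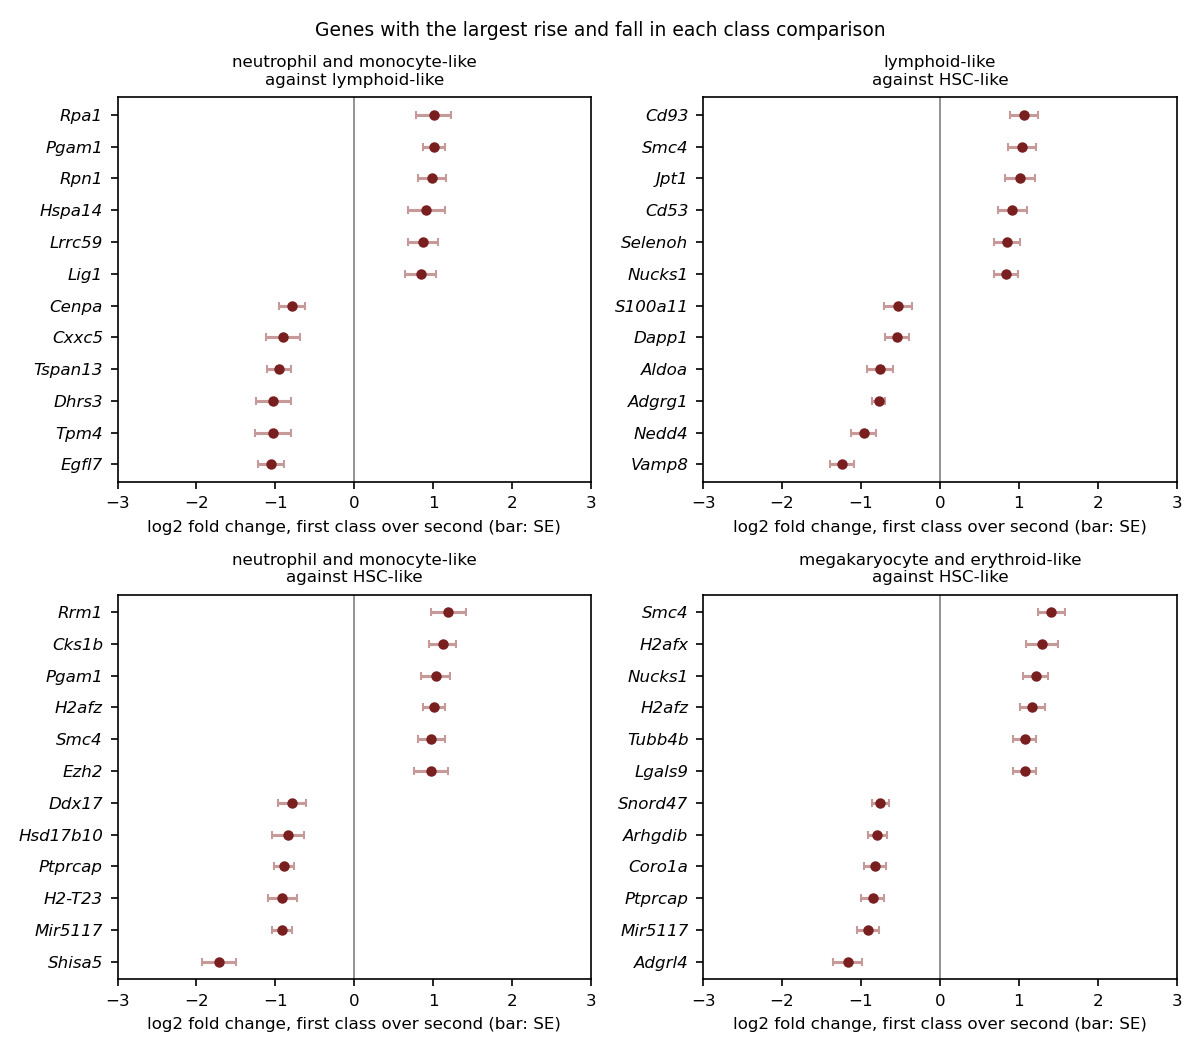
Log2 fold change of the 6 largest rises and 6 largest falls among called genes in each of the 4 class comparisons, first class over second, with points for the edgeR estimate and bars for its SE over 15 or 16 libraries. Smc4 stands at 1.04, 0.98 and 1.41 in the 3 comparisons against HSC-like cells, and Shisa5 has the lowest value drawn, -1.71.

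Neutrophil and monocyte-like cells had more transcripts of the tested G1 to S phase and G2 to M phase genes than HSC-like cells. They had fewer of Shisa5 and of mitochondrial ribosomal RNAs. Of 12 G1 to S phase genes 9 rose and 0 fell (9 adjusted over the list alone), among them the ribonucleotide reductase gene Rrm1 (log2 fold change 1.19 ± 0.22 SE, n = 15 libraries, adjusted p = 2.1e-05), Mcm5 (0.92 ± 0.19, adjusted p = 7.12e-05, higher in 15 of 15 libraries) and Pcna (0.75 ± 0.12, adjusted p = 5.26e-07, higher in 15 of 15 libraries). Of 5 G2 to M phase genes 4 rose (4 adjusted over the list alone), led by the cyclin-dependent kinase subunit gene Cks1b (1.12 ± 0.18, adjusted p = 5.29e-07, higher in 15 of 15 libraries). The histone variant gene H2afz rose by 1.01 ± 0.14 (adjusted p = 5.37e-08), and Ezh2, a histone methyltransferase gene, by 0.97 ± 0.22 (adjusted p = 0.000359). Of 7 glycolysis genes 3 rose (3 adjusted over the list alone), Pgam1, Pgk1 and Ldha, by 1.03, 0.67 and 0.38, without a call of the list (adjusted p = 0.137). Hsp90aa1 (0.60, adjusted p = 4.98e-07) and Cd53 (0.65, adjusted p = 0.0146) also rose.

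The largest fall was of Shisa5, a gene of the endoplasmic reticulum and nuclear membrane, at -1.71 ± 0.22 (adjusted p = 3.98e-09, 59.5 against 215 CPM, lower in 14 of 15 libraries). Of 7 MHC class I genes 4 were called lower (4 adjusted over the list alone), among them H2-T23 (-0.91 ± 0.18, adjusted p = 6.41e-05, lower in 12 of 15 libraries) and H2-K1 (-0.46 ± 0.08, adjusted p = 3.36e-06, lower in 10 of 15 libraries). The list was called lower by camera (adjusted p = 0.0466) but not with an estimated correlation (adjusted p = 0.141). Nor was it called at a minimum of 300 UMIs (adjusted p = 0.0691), at resolution 1.5 (0.202) or within batch SB343 (0.498), and without a filter on low counts its median was 0.01 where the median of all genes was 0.26. H2-D1 (-0.21, adjusted p = 0.0454) was lower in 8 and higher in 7 of 15 libraries, with a median of 837 CPM in neutrophil and monocyte-like against 830.4 CPM in HSC-like cells, so that its direction is not settled. It turned to 0.19 without a filter on low counts, and H2-Q7 (-0.46, adjusted p = 0.0351) to 0.06 within batch SB343. H2-D1 was not called without library 3, 8, 9, 11, 13, 14 or 16 (adjusted p = 0.0561 to 0.125), nor H2-Q7 without library 3, 4, 5, 6, 8 or 10 (0.0519 to 0.106). The list itself was not called without library 3, 4, 6 or 9 (adjusted p = 0.0634, 0.0721, 0.0644 and 0.0566). Mir5117, at -0.91, lies within Gas5 on the same strand, and Ptprcap, at -0.89, overlaps Coro1b, so that their UMIs cannot be assigned to either gene of the pair. mt-Rnr2 (-0.61 ± 0.04, adjusted p = 9.68e-22) and mt-Rnr1 (-0.45 ± 0.04, adjusted p = 2.99e-14) were lower in 15 of 15 libraries, whereas mt-Nd1, which overlaps mt-Ti, was higher in 15 of 15 (0.20 ± 0.04, adjusted p = 8.81e-05).

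Between these classes 279 of 871 genes were called by edgeR with Benjamini-Hochberg adjustment, 131 higher and 148 lower, 58 of them without a symbol. The G1 to S (adjusted p = 4.48e-05) and G2 to M lists (adjusted p = 0.00285) were called higher by camera and held with an estimated correlation (adjusted p = 0.0214 and 0.017), but the G1 to S list was not called at a minimum of 300 UMIs (adjusted p = 0.0691). Mitochondrially encoded transcripts, with 5 of 13 lower and 1 higher (5 and 1 adjusted over the list alone), were called lower (adjusted p = 0.016) but not with an estimated correlation (adjusted p = 0.141). Nor were they called in thinned cells (adjusted p = 0.457), at minimums of 300 and 1000 UMIs (0.882 and 0.112) or at resolution 1.5 (0.0568), and without a filter on low counts their median was 0.34 against 0.26 for all genes. Ribosomal protein genes had a median of -0.19, with 32 of 61 lower and 1 higher (36 and 2 adjusted over the list alone; camera adjusted p = 3.63e-09, and 0.000808 with an estimated correlation), but without a filter on low counts their median was 0.22 against 0.26 for all genes. Their list was not called in thinned cells (adjusted p = 0.215), and their share of all UMIs was not called different (median log2 ratio -0.03, permutation p = 0.174, adjusted p = 0.211). Thinned cells gave 29 calls among 172 genes tested, a minimum of 1000 UMIs 77 among 496, and no filter 667 among 16473. Of the last 635 were higher and 32 lower. Batch SB341 alone gave 166 calls and SB343 alone 107.

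Megakaryocyte and erythroid-like cells had more transcripts of the condensin gene Smc4, of the histone variant genes H2afx and H2afz and of the tested G2 to M phase genes than HSC-like cells. Smc4 rose by 1.41 ± 0.17 on the log2 scale (SE, n = 16 libraries, adjusted p = 3.18e-10). H2afx rose by 1.29 ± 0.20 (adjusted p = 2.68e-07, higher in 16 of 16 libraries) and H2afz by 1.17 ± 0.16 (adjusted p = 1.12e-08). Tubb4b rose by 1.07 ± 0.15 (adjusted p = 1.42e-08, higher in 16 of 16 libraries). All 3 tested G2 to M phase genes rose (3 adjusted over the list alone), as did Dut and Pcna of 4 G1 to S phase genes (2 adjusted over the list alone), too few for a list test. The galectin gene Lgals9 rose by 1.07 ± 0.14 (adjusted p = 6.1e-09, 531 against 238 CPM), and the chaperone gene Hsp90aa1 by 0.81 ± 0.10 (adjusted p = 7.32e-11), both higher in 16 of 16 libraries. Among 5 glycolysis genes Ldha rose (0.63 ± 0.10, adjusted p = 1.16e-06) while Pkm (-0.64 ± 0.16, adjusted p = 0.00118) and Aldoa (-0.62 ± 0.18, adjusted p = 0.00476) fell (1 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.784). The actin-binding coronin gene Coro1a fell by 0.83 ± 0.14 (adjusted p = 1.58e-06), Arhgdib by 0.79 ± 0.12 (adjusted p = 1e-07) and the adhesion receptor gene Adgrl4 by 1.17 ± 0.19 (adjusted p = 3.86e-07). Mir5117 (-0.91) and Snord47 (-0.75) lie in Gas5, a host gene of small nucleolar RNAs, and their UMIs cannot be told from those of Gas5.

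In this comparison edgeR with Benjamini-Hochberg adjustment called 225 of 552 genes, 100 higher and 125 lower, 56 of them without a symbol. Ribosomal protein genes had a median of -0.20, with 31 of 58 lower and 1 higher (33 and 1 adjusted over the list alone), and -0.08 without a filter on low counts, where the median of all genes was 0.09. The list was called lower by camera (adjusted p = 8.03e-09) and with an estimated correlation (adjusted p = 0.00136), and was not called in thinned cells (adjusted p = 0.187). Their share of all UMIs had a median log2 ratio of -0.084 (permutation p = 6.1e-05, adjusted p = 0.000208) and of -0.089 in thinned cells, lower in 13 of 16 libraries (permutation p = 0.00302, adjusted p = 0.00491). The small subunit gene Rps9 fell by 0.51 ± 0.05 (adjusted p = 4.83e-12, lower in 14 of 16 libraries). Mitochondrially encoded transcripts, with 6 of 13 lower and 1 higher (7 and 1 adjusted over the list alone), were called lower (adjusted p = 0.00739) but not with an estimated correlation (adjusted p = 0.103), in thinned cells (0.187) or at a minimum of 1000 UMIs (0.078), and their median without a filter on low counts was 0.09, the same as that of all genes. mt-Rnr2 fell by 0.64 ± 0.05 (adjusted p = 3.56e-19, lower in 16 of 16 libraries). Of 5 MHC class I genes Psmb8, a subunit of the immunoproteasome, fell (-0.52 ± 0.13, adjusted p = 0.000595), as did H2-D1 (-0.24) and H2-K1 (-0.18), each lower in 9 of 16 libraries (3 lower and 1 higher adjusted over the list alone). The list was not called (adjusted p = 0.444), and H2-D1 had 0.13 at a minimum of 1000 UMIs. H2-D1 was not called without library 6, 8, 9, 13, 14 or 16 (adjusted p = 0.0539 to 0.112), nor H2-K1 without library 1, 3, 4, 5, 6, 7, 8, 11 or 15 (0.0549 to 0.123). Thinned cells gave 22 calls among 156 genes tested, and batches SB341 and SB343 alone 115 among 535 and 139 among 683.

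Zc3h12a, Zc3h12c and Nfkbiz were too low to be tested between classes. Nfkbiz had 69 UMIs in neutrophil and monocyte-like cells against 26 in lymphoid-like cells of 15 libraries, and 11 in megakaryocyte and erythroid-like against 12 in HSC-like cells of 16 libraries. Zc3h12a had 26 and 10 UMIs in the first of these pairs and 7 and 8 in the second, and Zc3h12c 17 and 18, and 5 and 8. The classes differ in UMIs per cell, and no difference is read from these counts.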

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

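All tests in this part except that of the mix of cell classes were chosen after the result was seen. Spike-in transcripts were found only in LSK library 2, with 12 UMIs in 10 wells and at most 2 in a well, which is above the 3 counts that a count of 0 allows. The other 15 libraries had 0 UMIs of the 92 spike-in entries. No biological explanation applies to added RNA, and the source of these 12 UMIs was not tested.

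The number of called genes was set against 100 swaps of the class labels within libraries, the real labels included. Between neutrophil and monocyte-like and lymphoid-like cells, 1 of 100 gave as many calls as the real 177, and the highest other gave 30. Between lymphoid-like and HSC-like cells, 1 of 100 gave as many as 88, and the highest other gave 7. For neutrophil and monocyte-like against HSC-like cells it was 1 of 100 for 279 calls, with 55 as the highest other. For megakaryocyte and erythroid-like against HSC-like cells it was 1 of 100 for 225 calls, with 89. The highest others had the labels of 2 or 3 libraries swapped. Cells were placed in classes by their own expression, so swapped labels give fewer calls by construction, and the swaps neither exclude chance nor speak for it.

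The Nfkbiz level differed between libraries, from 0 to 52.0 CPM. If sequencing batch were the whole cause, no library of batch SB341 would reach the lowest of batch SB343 (19.0 CPM); 2 of the 9 SB341 libraries did, which argues against it. The mix of cell classes, at 1 rate per cluster, predicted 17.5 to 22.1 CPM, 8.88% of the observed range, which argues against it too. No biological explanation was tested, because the genotype, mouse and sort of each library are not given in the sources used here; these stay open.

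G1 to S phase genes took a higher share of UMIs in neutrophil and monocyte-like than in lymphoid-like cells, with a median log2 ratio of 0.52 (permutation p = 0.00012). Neutrophil and monocyte-like cells held more UMIs per cell, which could raise the share if deeper cells yielded more of these genes. In 322 pairs of cells matched within 10% in UMIs per cell in the same library, the ratio was 0.519, higher in 14 of 15 libraries (permutation p = 0.00018), which argues against UMIs per cell as the whole cause. How cells were clustered may set part of the size: with clusters made without histone and state genes the median log2 fold change of the list was 0.27 (13 genes tested) against 0.47 (23 genes), and different genes and cells enter the comparison, so that the share due to clustering stays open.

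Ribosomal protein genes were lower in megakaryocyte and erythroid-like than in HSC-like cells. Without any scaling factor their share of all UMIs still had a median log2 ratio of -0.084, lower in 15 of 16 libraries (permutation p = 6.1e-05), which argues against scaling of the sums as the whole cause. With 276 named ribosomal pseudogenes added the ratio was -0.097 (permutation p = 0.00015), which argues against UMIs lost to pseudogenes. A difference in differentiation or growth between the classes may contribute, as a hypothesis; simulated unchanged genes in this comparison had a median of -0.07 in scaled values, about the size of the fall in share, and the share in simulated counts was not computed.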

How the results depend on the processing

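The comparisons between classes and all their alternatives were chosen after the data were seen; the alternatives for values per library were planned. The planned knockout against control comparisons and their alternatives were not run, because no genotype is given in the sources used here. At resolution 0.5, with pooled variable genes and without histone and state genes no HSC-like class formed, so none of the 3 comparisons against it could be made, and resolution 0.5 lacked the lymphoid-like class as well, which left no comparison. The cause of the changes listed here was not tested, except that thinning and single batches leave fewer genes or libraries to test by construction. Other settings also left fewer pairs of libraries. Of 15 pairs between neutrophil and monocyte-like and lymphoid-like cells, 4 remained with pooled variable genes and 12 at a minimum of 1000 UMIs. There were 13 at 300 UMIs and at resolution 1.5, and 14 without histone and state genes. Against HSC-like cells, 11 of 15 neutrophil and monocyte-like pairs remained at 1000 UMIs. DESeq2, RLE factors and sums without mitochondrial and ribosomal genes left each count of calls within 1.5 times, and of 163 named fold changes DESeq2 kept 155 on the same side of the threshold with their direction and RLE 162. Of the named fold changes called and tested again, the call ended, with the direction kept, for 8 of 122 with DESeq2, 36 of 122 without a filter, 19 of 122 with no block, 42 of 111 in SB343, 19 of 114 in SB341, 16 of 103 and 19 of 91 at UMI minimums of 300 and 1000, 5 of 94 at resolution 1.5, 15 of 40 in thinned cells, 15 of 28 with pooled variable genes and 6 of 26 without histone and state genes. Of called lists tested again, the call ended for 4 of 7 in thinned cells, where 1 more turned and was not called, 4 of 13 and 3 of 11 at minimums of 300 and 1000, 2 of 12 at resolution 1.5, 4 of 14 in SB343, 1 of 4 with pooled variable genes and 5 of 14 with an estimated correlation. Low counts limit most genes, since only 552 to 1476 could be tested.

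Called genes between neutrophil and monocyte-like and lymphoid-like cells (177) came to 19 in thinned cells, 80 and 86 at UMI minimums of 300 and 1000, 108 at resolution 1.5, 62 with pooled variable genes, 81 without histone and state genes, 97 without a low count filter, 81 with no replicate block, 71 in SB341 and 61 in SB343. For lymphoid-like against HSC-like cells (88) they came to 8 thinned, 363 without a filter, 37 with no replicate block and 6 in SB343. For neutrophil and monocyte-like against HSC-like cells (279) they came to 29 thinned, 77 at a minimum of 1000, 164 at resolution 1.5, 667 without a filter, 169 with no replicate block, 166 in SB341 and 107 in SB343. For megakaryocyte and erythroid-like against HSC-like cells (225) they came to 22 thinned, 145 at a minimum of 1000, 133 with no replicate block, 115 in SB341 and 139 in SB343. Without a filter the calls split 68 higher and 29 lower in the first comparison, 331 and 32 in the second, 635 and 32 in the third and 237 and 51 in the last, while the median of all genes moved to 0.05, 0.20, 0.26 and 0.09. These counts come from unlike numbers of genes tested. In thinned cells 191, 170, 172 and 156 genes were tested in the same order, and without a filter 16856, 16096, 16473 and 15725. Of the main calls, 59, 34, 101 and 98 could be tested in thinned cells. Of those, 57, 34, 96 and 84 kept their direction, and 18, 8, 27 and 18 were called again. Leaving out 1 library at a time gave 153 to 193, 64 to 105, 249 to 289 and 205 to 240 calls in the same order.

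The median share of HSC-like cells was 15.8% at a minimum of 300 UMIs and 6.12% at resolution 1.5, that of lymphoid-primed progenitor-like cells 5.17% at 300, and that of megakaryocyte and erythroid progenitor-like cells 25.7% at resolution 0.5. Cells kept came to 347.5 per library at 300 and 235 at 1000, where the median UMIs per kept cell was 1943.5. Fold changes that turned were Tyrobp (-0.20) and Hspe1 (-0.06) with pooled variable genes in the first comparison. That fit had 4 pairs of libraries and called neither gene (adjusted p = 0.854 and 0.915). Without a filter, Rps9 (0.03), Rpl37a (0.05) and Rps19 (0.08) turned in lymphoid-like against HSC-like cells, and H2-D1 (0.19), Rps14 (0.03), Rpl32 (0.11), Rpl23 (0.08) and mt-Co1 (0.04) in neutrophil and monocyte-like against HSC-like cells. H2-Q7 turned there in SB343 (0.06), and H2-D1 in megakaryocyte and erythroid-like against HSC-like cells at minimums of 300 (0.02) and 1000 (0.13). In thinned cells the ribosomal list of lymphoid-like against HSC-like cells turned to higher (adjusted p = 0.533). Leaving out 1 library ended the call of 9 named fold changes, each without a change of direction. In the first comparison these were Tyrobp (without library 3, 4, 6, 11 or 16; highest adjusted p = 0.0891), Pgk1 (5, 6, 8, 12 or 14; 0.0873) and Hspe1 (7, 8 or 16; 0.058). In lymphoid-like against HSC-like cells it was S100a11 (1, 3, 6, 7, 8, 9 or 13; 0.0824). In neutrophil and monocyte-like against HSC-like cells they were H2-D1 (3, 8, 9, 11, 13, 14 or 16; 0.125), H2-Q7 (3, 4, 5, 6, 8 or 10; 0.106) and Lbr (3, 7 or 11; 0.0592). In megakaryocyte and erythroid-like against HSC-like cells they were H2-K1 (1, 3, 4, 5, 6, 7, 8, 11 or 15; 0.123) and H2-D1 (6, 8, 9, 13, 14 or 16; 0.112).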

Other observations

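The values and tests in this part were chosen after the data were seen. Transcripts of a few genes lay in separate ranges over the 16 libraries, given here in the order of LSK libraries 1 to 16 with no explanation. Nfkbiz stood at 5.21, 6.00, 5.16, 1.77, 4.76, 0, 0, 2.77, 40.8, 52.0, 45.9, 34.6, 40.3, 33.7, 26.7 and 19.0 CPM. Tfrc, the transferrin receptor gene, stood at 35.2, 28.0, 40.0, 31.9, 27.0, 26.8, 33.3, 26.3, 92.2, 116, 114, 75.3, 110.5, 71.0, 82.0 and 106 CPM. Xist, the RNA that silences an X chromosome in female cells, had 7, 1, 8, 4, 5, 6, 10 and 34 UMIs in libraries 1 to 8 and 0 in libraries 9 to 16. The share of neutrophil and monocyte progenitor-like cells was 8.96%, 2.75%, 6.36%, 4.76%, 5.71%, 7.35%, 8.23%, 6.73%, 19.1%, 15.7%, 23.8%, 26.4%, 20.5%, 21.96%, 19.1% and 26.4%. The share of megakaryocyte and erythroid progenitor-like cells was 3.88%, 5.81%, 5.76%, 6.67%, 5.40%, 5.43%, 4.57%, 5.13%, 11.3%, 13.02%, 15.5%, 10.1%, 12.8%, 13.5%, 12.2% and 8.47%. Lymphoid-primed progenitor-like cells ran the other way, from 12.06% to 20.43% in libraries 1 to 8 and from 7.04% to 12.2% in libraries 9 to 16, with ranges that overlapped. No label gives the genotype, the mouse or the sort of these libraries. Libraries 1 to 8 and 9 to 16 were set apart only to state ranges, and these sets were not averaged or tested.

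Between the named classes, mitochondrially encoded transcripts took a smaller share of UMIs in each class than in HSC-like cells, without any scaling factor. The median log2 ratio of their share was -0.18 in lymphoid-like cells (lower in 14 of 16 libraries, permutation p = 0.000214). It was -0.23 in neutrophil and monocyte-like cells (lower in 15 of 15, p = 6.1e-05 by permutation, the smallest it can give) and -0.31 in megakaryocyte and erythroid-like cells (lower in 16 of 16, permutation p = 3.05e-05, the smallest it can give). Over 17 tests the adjusted p were 0.000519, 0.000208 and 0.000208. The ribosomal RNAs mt-Rnr2 and mt-Rnr1 make up most of these transcripts, at a median of 48460 and 27330 CPM over libraries.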
